A study of Mus musculus with 12 samples.

How the data were processed

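The 12 4C-seq libraries cover 3 viewpoints (Mycn enhancer, Ets1 promoter, Tbx3 enhancer), each with 2 ES and 2 MEF libraries. Per the labels' protocols, formaldehyde-fixed chromatin was cut with DpnII, ligated, cut again with Csp6I and religated. DpnII cuts a site of a few bases, so contacts are seen only at fragments between such sites, and a sequence variant in a site can change which fragments are seen. The submitters' processing notes name Bowtie 1.0.0, edgeR and the mouse build mm10 without saying what each was used for. Whether duplicate reads were removed, how windows were counted and which windows were left out is not given in the sources used here.

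The deposited tables hold CPM by name, 1 table per viewpoint with a column for each of its 4 libraries, in 10 kb windows that step by 1 kb along the viewpoint chromosome. All values of a library were whole multiples of 1 step (100% of values in each of the 12 libraries, within a tolerance of 0.01 count), and 1000 divided by that step was a whole number. The values are therefore read here as counts per 1000 of a library total, and that number as the total. The scale is worked out from the values and not stated anywhere, and it cancels in fold differences except through the pseudocount and the filter. The tables listed 7348 windows for the Mycn enhancer, 8207 for the Ets1 promoter and 1750 for the Tbx3 enhancer, and each listed window had counts in at least 3 of the 4 libraries. Windows with counts in fewer libraries, such as those contacted in 1 cell type alone, were not analysed here.

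Groups were taken from the sample titles. The viewpoint was placed at the window with the highest mean over the 4 libraries, because the labels give no coordinates: chromosome 12, 12786001 to 12796000; chromosome 9, 32698001 to 32708000; and chromosome 5, 119582001 to 119592000. Windows with a value of at least 1 in at least 2 of the 4 libraries were kept, which left 1107, 1051 and 1228. ES and MEF libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment within a viewpoint at 0.05. All log2 differences are ES minus MEF on this log2(value + 1) scale, which understates the change of low values, and peak window means with SD are counts per 1000. The median log2 difference over tested windows was -0.15 for the Mycn enhancer, -0.20 for the Ets1 promoter and -0.32 for the Tbx3 enhancer, and calls are made against 0, not against that shift. The recovered counts were also tested with edgeR 4.0.16 (quasi-likelihood test), which called 339 windows for the Mycn enhancer, 368 for the Ets1 promoter and 37 for the Tbx3 enhancer, of which 327, 360 and 16 were also called by limma in the same direction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

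The design fixed before the data were examined tested promoters, as 10 kb on each side of the transcription start. The gene table used here (GRCm38.p6, the assembly that mm10 names) gives each gene's start and end but not its strand, so a start of transcription could not be placed. Gene loci were tested in place of promoters: the mean of all windows that overlap the gene with 10 kb on each side, with the same filter and test. Loci under 10 kb from the viewpoint, among them Ets1 and AW549542, were left out. Either gene end in place of the gene was added as an alternative. The planned distance to the nearest transcription start became the distance to the nearest gene.

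Named items followed a rule also fixed before. Called windows of 1 direction no more than 20 kb apart were merged into regions, and a region counted where, at its window of smallest p, both ES libraries lay on 1 side of both MEF libraries. Up to 10 regions and 10 gene loci per viewpoint and direction with the largest log2 difference may be named. In addition, 3 lists of genes that flank the viewpoints are always reported. The lists named 21 genes around Mycn, 31 around Ets1 and 22 around Tbx3. All matched the gene table except Mycnos, and Fam49a and Cyria are 1 gene there. Of these, 19, 30 and 19 had windows and 3, 3 and 7 passed the filter.

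Replicate pairs were compared by a chi-square test of their counts in windows that do not overlap. Every pair differed by more than sampling noise except the ES pair of the Tbx3 enhancer (chi-square 53.7 on 50 degrees of freedom, p = 0.334). At 379 counts the test could not decide whether both are 1 library: MEF replicate 1 thinned to that depth differed from MEF replicate 2, another library of its group, in 27 of 100 draws, and from ES replicate 1, a library of the other group, in 90 of 100. The pair was kept as 2 replicates, with both summed as 1 as an added alternative. Pearson's r of log2 values between replicates, across windows that are not independent, was 0.96 (ES) and 0.93 (MEF) for the Mycn enhancer, 0.96 and 0.92 for the Ets1 promoter, and 0.63 and 0.77 for the Tbx3 enhancer.

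Shares within 200 kb are percentages of the listed window values and were compared by a two-sided exact permutation test. Listed windows held between 63.4% and 76.6% of each library total. A floor of 3 counts was 0.0341 to 0.179 per 1000 for the Mycn enhancer, 0.0145 to 0.22 for the Ets1 promoter and 0.461 to 7.92 for the Tbx3 enhancer. These floors and the binomial intervals cover counting error only, since PCR reads are not independent molecules.

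The tests were checked on simulated counts drawn from the means and totals of each viewpoint, with 200 windows changed. Each window was drawn on its own and the changed ones were picked at random. Real neighbouring windows overlap, so the check does not cover how the tests behave under that dependence. At a fold of 2, limma recovered 61% of the changed windows among 1107 for the Mycn enhancer, 56% among 1051 for the Ets1 promoter and 1.5% among 1228 for the Tbx3 enhancer. At a fold of 4 it recovered 98%, 95% and 45.5%. Alternatives tried were other pseudocounts (0.25 and 10), no filter, median centring, rescaling without windows within 50 kb, quantile normalization, eBayes without a trend, a replicate block, leaving out each library, bins of 20 kb, windows within 2 Mb, locus flanks of 5 and 25 kb, and other definitions of the share. Rescaling was to a common total and not to the CPM scale first planned, so that the filter and pseudocount kept their meaning. Added after the data were seen were windows that do not overlap, thinning to equal totals, gene ends, shares of the library total, and for the Tbx3 enhancer edgeR without ES replicate 2 and the summed ES libraries.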

Results

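Chromatin contacts of 3 genomic sites were measured by 4C-seq, in which fixed chromatin is cut and religated and all fragments joined to 1 chosen site, the viewpoint, are amplified and sequenced. The viewpoints were a Mycn enhancer on chromosome 12, the Ets1 promoter on chromosome 9 and a Tbx3 enhancer on chromosome 5. Each was assayed in 2 libraries of mouse embryonic stem (ES) cells grown in 2i medium and 2 libraries of uninduced mouse embryonic fibroblasts (MEFs) that carry a doxycycline-inducible cassette of reprogramming factors, 12 libraries in all. The labels name the ES cells as the V6.5 line, except for ES replicate 2 of the Tbx3 enhancer, whose label names no line. The design text of the series presents 4C-seq at these sites as a follow-up of genome-wide contact maps, so the question at each viewpoint was which contacts differ between ES cells and MEFs. Values are counts per 1000 of the library total, in 10 kb windows that step by 1 kb along the viewpoint chromosome. For the Mycn enhancer the library totals were 88038 and 27290 counts in ES replicates 1 and 2, and 16774 and 59424 in MEF replicates 1 and 2. For the Ets1 promoter they were 70629 and 206874 in ES cells and 13629 and 29638 in MEFs. The Tbx3 enhancer was far shallower, with 6507 and 379 counts in ES cells and 2871 and 5342 in MEFs, so that 1 count in ES replicate 2 is worth 2.64 per 1000. Nothing states that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The limma test also pools this spread over the windows or loci of a viewpoint, many of which overlap. Very small p-values from 2 libraries per group rest on that pooling and may be too small.

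From the Mycn enhancer, ES cells contacted the Mycn gene more than MEFs did. Mycn encodes a MYC-family transcription factor and lies 145 kb from the viewpoint, at chromosome 12, 12936093 to 12941836 (mm10). Its locus, the gene with 10 kb on each side, held 16.8 ± 0.18 counts per 1000 per window in ES cells and 5.91 ± 0.06 in MEFs (SD, n = 2 each), a 2.84-fold difference. The log2 difference was 1.37 (SE 0.06, limma adjusted p = 4.0e-05). The called windows around it joined into a region of 217 kb, from 12797001 to 13014000, which reaches from the viewpoint past Mycn and also covers Gm40271 and Gm35208. In the window with the smallest p in this region, 12934001 to 12944000, ES cells had 30.2 ± 1.46 and MEFs 6.51 ± 0.27 counts per 1000 (SD, n = 2 each), a log2 difference of 2.05 (SE 0.13, limma adjusted p = 4.2e-10).

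On the other side of the viewpoint, toward lower coordinates, 132 called windows were higher in MEFs and 12 in ES cells. The longest MEF-higher region there spanned 180 kb, from 12422001 to 12602000, over the long noncoding RNA gene Gm34489. Its peak window held 1.61 ± 0.05 counts per 1000 in ES cells and 6.03 ± 0.24 in MEFs (SD, n = 2 each), a log2 difference of -1.43 (limma adjusted p = 0.000227). Nearer the viewpoint, a short region from 12617001 to 12629000 was higher in ES cells, with 5.07 ± 0.66 against 2.53 ± 0.30 in MEFs at its peak (SD, n = 2 each; limma adjusted p = 0.0203). Next to it, MEFs were higher from 12643001 to 12672000, with 5.23 ± 0.43 in ES cells and 9.89 ± 0.50 in MEFs at the peak (SD, n = 2 each; limma adjusted p = 0.000988). A further MEF-higher region, from 12743001 to 12798000, included the viewpoint window and held 28.1 ± 3.62 in ES cells and 45.4 ± 0.62 in MEFs at its peak (SD, n = 2 each). Beyond Mycn, MEFs were higher from 13090001 to 13186000, with 1.49 ± 0.45 counts per 1000 in ES cells and 3.96 ± 0.48 in MEFs at the peak (SD, n = 2 each), whereas ES cells were higher in 15 kb, from 13240001 to 13255000, that overlap the higher-coordinate end of Ddx1, which encodes an RNA helicase (log2 difference 1.21). Both directions occurred within Nbas, a gene of retrograde vesicle transport, with 1.23 ± 0.19 in ES cells and 0.416 ± 0.25 in MEFs at 13341001, and 0.259 ± 0.003 and 1.52 ± 0.13 at 13403001 (SD, n = 2 each). A distant ES-higher region at Smc6, which encodes a chromosome maintenance protein, peaked 1505 kb from the viewpoint with 1.43 ± 0.16 counts per 1000 in ES cells and 0.131 ± 0.10 in MEFs (SD, n = 2 each). Without ES replicate 1 or ES replicate 2 that peak window failed the filter and was not tested. The remaining MEF-higher regions began at 11352001 (Vsnl1), 11975001, 12189001, 12342001 (Cyria) and 13042001, with log2 differences from -0.70 to -0.96, and each lost its call without ES replicate 2 (adjusted p from 0.0523 to 0.0817). Those at 11352001, 12342001 and 13042001 also ended without the filter (0.21, 0.0585 and 0.108), with median-centred values (0.156, 0.21 and 0.204), with quantile normalization (0.164, 0.224 and 0.216), without ES replicate 1 (0.106, 0.213 and 0.279) and in other alternatives. Of the other calls, that of the short ES-higher region ended without a filter (adjusted p = 0.0967), without ES replicate 1 (0.0715), ES replicate 2 (0.185) or MEF replicate 1 (0.0633). The call at 13090001 ended with median-centred values (0.078), with quantile normalization (0.0863), without ES replicate 2 (0.102) or without MEF replicate 1 (0.0605). That at Ddx1 ended without ES replicate 1 (0.0877), and that over the viewpoint with quantile normalization (0.107). The ES-higher call in Nbas ended in 6 alternatives, among them without MEF replicate 1 (0.075) and without MEF replicate 2 (0.332).

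**Figure D1:**
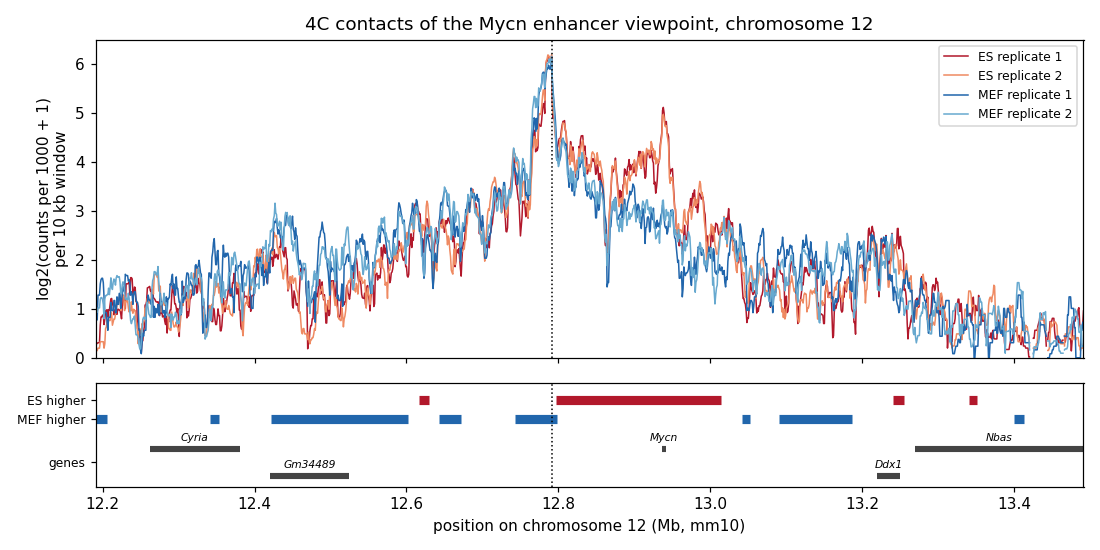
Contact profiles of the Mycn enhancer in the 4 libraries, as log2(counts per 1000 + 1) per 10 kb window against position on chromosome 12 in Mb, with called regions and genes drawn to scale beneath and the viewpoint as a dotted line. Both ES lines lie above both MEF lines at Mycn, where the peak window held 30.2 counts per 1000 in ES cells and 6.51 in MEFs.

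Of 1107 windows tested from the Mycn enhancer, limma called 339 at the 0.05 threshold, 182 higher in ES cells and 157 higher in MEFs, in 5 and 10 regions. Neighbouring windows share most of their sequence, so these are not independent calls. The list of genes around Mycn had 19 members with windows, of which 3 passed the filter on low values. Among these 3, Mycn was higher in ES cells, Cyria, which encodes a Rac-binding protein, was lower, and Ddx1 did not pass the test. Cyria held 1.19 ± 0.06 counts per 1000 in ES cells and 1.67 ± 0.17 in MEFs (SD, n = 2 each; limma adjusted p = 0.0246), and Ddx1 held 3.14 ± 0.27 and 2.55 ± 0.13 (adjusted p = 0.0538). Adjusted over the list alone, 2 of the 3 genes were higher in ES cells and 1 was higher in MEFs. The Cyria call ended with median-centred values (adjusted p = 0.82), with quantile normalization (0.532), without the filter (0.148), with a 5 kb flank (0.094), and without ES replicate 1 (0.184), ES replicate 2 (0.148) or MEF replicate 1 (0.203). Its difference reversed to 0.088 at the lower-coordinate gene end. Over all gene loci, 18 of 24 were called, 7 higher in ES cells and 11 in MEFs. The split of window calls depended on the scaling, at 240 ES-higher and 36 MEF-higher with median-centred values and 152 and 180 after rescaling without windows within 50 kb. The window count was 221 without ES replicate 2 and 216 without MEF replicate 1. The locus count was 8 without ES replicate 1 and 8 without ES replicate 2.

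From the Ets1 promoter, ES cells had more contact with the distant Kcnj5 and Kcnj1 loci, and MEFs had more contact around Gm31871 and in most called windows on the other side of the viewpoint. Ets1 encodes an ETS-family transcription factor, and the viewpoint window, 32698001 to 32708000 on chromosome 9, lies within the gene. Toward lower coordinates ES cells were higher across 184 kb, from 32210001 to 32394000, over part of Arhgap32 and over the potassium channel genes Kcnj5 and Kcnj1. At the peak window of this region ES cells held 2.17 ± 0.38 counts per 1000 (SD, n = 2), while MEF replicate 1 had no counts and MEF replicate 2 had 0.202 per 1000. The log2 difference there was 1.52 (SE 0.24, limma adjusted p = 0.00209). Without ES replicate 1 or ES replicate 2 this window failed the filter and was not tested. MEFs were higher in 82 windows that merged into a region of 199 kb spanning the viewpoint, from 32569001 to 32768000, and in 4 regions between 32809001 and 33255000. Within that span, 3 windows next to the viewpoint, from 32687001 to 32699000, were higher in ES cells, with 23.8 ± 2.57 against 15.7 ± 4.16 in MEFs at the peak (SD, n = 2 each; limma adjusted p = 0.0221). This call ended without the trend (0.0882), after thinning (0.0807), among windows that do not overlap (0.0617), and without ES replicate 1 (0.274) or ES replicate 2 (0.0589). The 199 kb MEF-higher region peaked 107 kb away toward lower coordinates, between the viewpoint and Kcnj1, at Gm31871, a long noncoding RNA gene, with 8.49 ± 0.56 counts per 1000 in ES cells and 27.8 ± 1.45 in MEFs (SD, n = 2 each), a log2 difference of -1.60 (SE 0.15, limma adjusted p = 0.000152).

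These 4 regions on the higher-coordinate side overlapped no protein-coding gene. That from 32929001 to 33028000 overlapped no annotated gene and had 3.15 ± 0.41 counts per 1000 in ES cells and 10.1 ± 0.77 in MEFs at its peak (SD, n = 2 each). The next, from 33053001 to 33163000, overlapped Gm27166, with 2.10 ± 0.05 in ES cells and 6.03 ± 0.08 in MEFs. That from 33196001 to 33255000 overlapped Gm32171, with 1.82 ± 0.29 and 6.33 ± 1.59. That from 32809001 to 32839000 overlapped Gm3331, with 3.71 ± 0.50 and 10.1 ± 1.64. Farther out, MEFs were higher at St3gal4, a sialyltransferase gene, and at Dcps, a gene of mRNA decay, more than 2 Mb away and with low values. ES cells were also higher in 2 stretches within Fli1, another ETS-family gene, with log2 differences of 1.14 and 1.02, and in 2 single windows at Barx2, a homeobox gene, where neither MEF library exceeded 0.293 counts per 1000. The Barx2 windows failed the filter without ES replicate 1 or ES replicate 2 and were not tested there. Beside Fli1, from 32546001 to 32564000, ES cells held 4.76 ± 0.19 and MEFs 2.02 ± 0.05 at the peak (SD, n = 2 each; limma adjusted p = 0.0106), a call that ended without ES replicate 1 (0.191) or ES replicate 2 (0.196). The other ES-higher regions began at 31669001, 31940001 and 33265001, with log2 differences of 1.03, 1.05 and 0.81, and the last ended without the filter (adjusted p = 0.141), with quantile normalization (0.166) and after thinning (0.059), the second with quantile normalization (0.0721). Their peak windows also failed the filter without ES replicate 1 or ES replicate 2 and were not tested there. The Fli1 calls ended without ES replicate 1 (limma adjusted p = 0.304 and 0.191), the second also without ES replicate 2 (0.196), and the Barx2 calls with quantile normalization (0.053 and 0.0952). Those at St3gal4 and Dcps ended without the filter (0.0764 at St3gal4, 0.363 and 0.0709 at Dcps), without ES replicate 1 (0.387, 0.6 and 0.304) and without ES replicate 2 (0.234, 0.356 and 0.3). The first Dcps call, at 35136001, also ended with edgeR (adjusted p = 0.119), a pseudocount of 0.25 (0.0831), median-centred values (0.146) and thinning (0.195), and the second after thinning (0.0516).

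**Figure D2:**
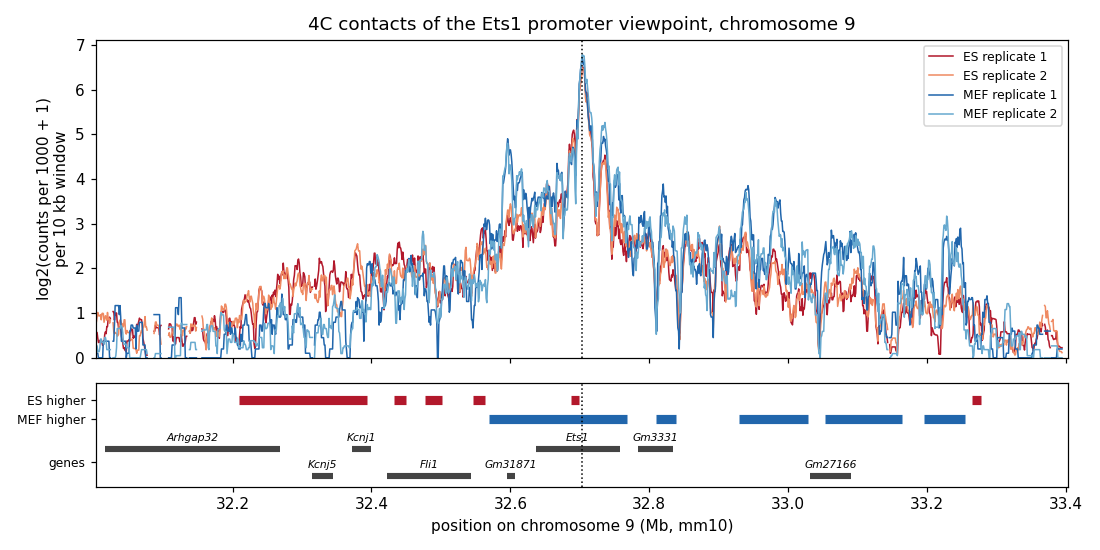
Contact profiles of the Ets1 promoter in the 4 libraries, as log2(counts per 1000 + 1) per 10 kb window against position on chromosome 9 in Mb, with called regions and genes drawn to scale beneath and the viewpoint as a dotted line. ES lines lie above MEF lines over Kcnj5 and Kcnj1, and MEF lines lie above ES lines at Gm31871, where the means were 27.8 and 8.49 counts per 1000.

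Of 1051 windows tested from the Ets1 promoter, limma called 414, with 162 higher in ES cells and 252 higher in MEFs, in 10 and 8 regions. The list of genes around Ets1 had 30 members with windows, of which 3 passed the filter, and all 3 were higher in ES cells. Kcnj5 held 2.06 ± 0.41 counts per 1000 in ES cells and 0.541 ± 0.06 in MEFs, a 3.80-fold difference, and Kcnj1 held 2.51 ± 0.05 and 1.37 ± 0.07 (SD, n = 2 each; limma adjusted p = 0.00176 for both). Fli1 held 2.81 ± 0.01 and 2.16 ± 0.26 (adjusted p = 0.0316). The Fli1 call ended with median-centred values (adjusted p = 0.318), with quantile normalization (0.347), without the filter (0.434) and without either of ES replicate 1 (adjusted p = 0.206) and ES replicate 2 (0.14). The Kcnj5 call ended with quantile normalization (adjusted p = 0.182), and the Kcnj1 call at the higher-coordinate gene end (0.087) and without ES replicate 1. Without ES replicate 1 or ES replicate 2, the Kcnj5 locus failed the filter, so its call was not tested there. Adjusted over the list alone, the 3 genes were again higher in ES cells. Of 13 gene loci tested, 12 were called, 7 higher in ES cells and 5 in MEFs. The latter were the noncoding genes Gm31871, Gm27166, Gm31928, Gm3331 and Gm27162, of which Gm31928 reversed to 0.26 under quantile normalization and Gm27166 alone was still called without ES replicate 1. The split of window calls was 194 ES-higher and 177 MEF-higher with median-centred values, 188 and 127 after rescaling without windows within 50 kb, and 116 and 123 with quantile normalization. Without ES replicate 1 the window count was 74, with 2 higher in ES cells, and without ES replicate 2 it was 86, with 1 higher in ES cells. Only 304 of the 414 called windows passed the filter in either case. The locus count was 1 without ES replicate 1 and 6 without ES replicate 2.

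From the Tbx3 enhancer, ES cells contacted Tbx3 more than MEFs did. Tbx3 encodes a T-box transcription factor and lies 83.5 kb from the viewpoint, at chromosome 5, 119670534 to 119684724. Its locus held 14.2 ± 0.20 counts per 1000 per window in ES cells and 5.27 ± 0.23 in MEFs (SD, n = 2 each), a 2.69-fold difference with a log2 difference of 1.28 (SE 0.16, limma adjusted p = 8.1e-10). In a window of ES replicate 2, 1 count is worth 2.64 per 1000, so the SD of the ES pair may understate counting error. The region of called windows spanned 37 kb, from 119655001 to 119692000, and also overlapped the noncoding gene Tbx3os2 and parts of Gm16064 and Tbx3os1. In its peak window ES cells had 26.7 ± 3.24 and MEFs 5.29 ± 1.39 counts per 1000 (SD, n = 2 each), a log2 difference of 2.15 (SE 0.35, limma adjusted p = 9.9e-07). The window held 11 counts in ES replicate 2. A second ES-higher region of 12 kb, from 119370001 to 119382000, overlapped no gene and peaked at 12.8 ± 4.35 in ES cells and 3.00 ± 0.79 in MEFs (SD, n = 2 each; limma adjusted p = 0.0275); edgeR did not call it (adjusted p = 0.0502). Neither did limma without the filter (0.0554), with quantile normalization (0.383), without the trend (0.411), with the ES libraries summed (0.308), or without ES replicate 2 (0.352), MEF replicate 1 (0.607) or MEF replicate 2 (0.31).

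**Figure D3:**
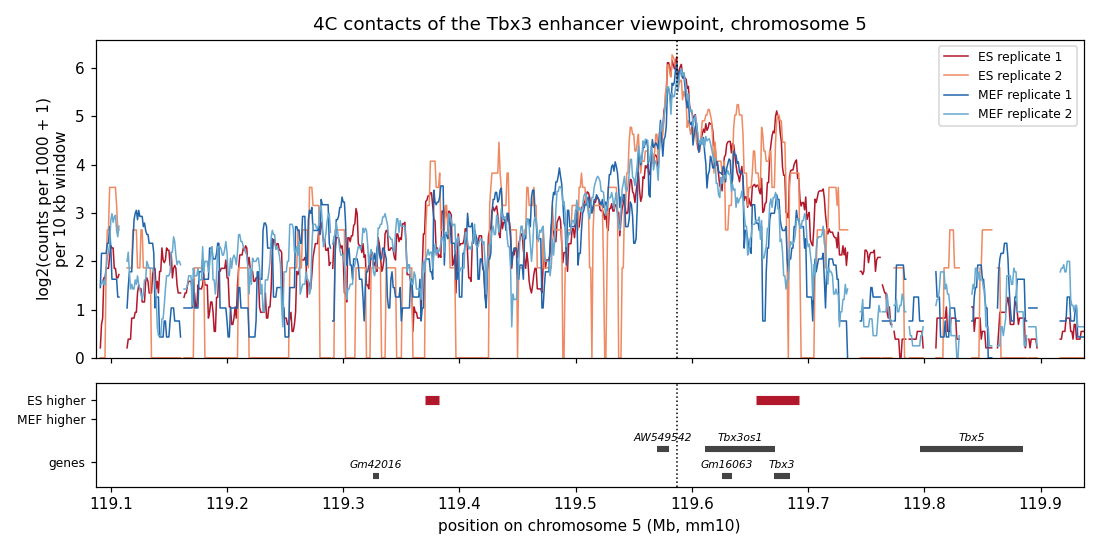
Contact profiles of the Tbx3 enhancer in the 4 libraries, as log2(counts per 1000 + 1) per 10 kb window against position on chromosome 5 in Mb, with called regions and genes drawn to scale beneath and the viewpoint as a dotted line. Both ES lines lie above both MEF lines at Tbx3 (26.7 and 5.29 counts per 1000 at the peak window), and ES replicate 2, with 379 counts, moves in steps.

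The list of genes around Tbx3 had 19 members with windows, of which 7 passed the filter, and 4 of the 7 were higher in ES cells. Besides Tbx3 these were its noncoding neighbours Tbx3os2 (11.9 ± 1.93 in ES cells, 4.73 ± 0.05 in MEFs), Tbx3os1 (18.8 ± 1.09 and 11.9 ± 0.07) and Gm16063 (18.8 ± 2.22 and 12.8 ± 0.66; SD, n = 2 each). Their loci overlap, so the 4 calls share windows. Tbx5, another T-box gene, held 0.899 ± 0.47 in ES cells and 1.23 ± 0.27 in MEFs, and Rbm19 and Med13l likewise did not pass (adjusted p = 0.968 and 0.809), at a depth where 3 counts in ES replicate 2 are 7.92 per 1000. Adjusted over the list alone, 4 genes were higher in ES cells and 0 in MEFs. Over all 34 loci tested, limma called 5, the fifth being Gm16064, with 0 higher in MEFs and 7 at an unadjusted p under 0.05. Of 1228 windows limma called 21, all higher in ES cells, with 149 at an unadjusted p under 0.05, while edgeR on the recovered counts called 37, 28 higher in ES cells and 9 in MEFs. No window was called by limma with quantile normalization, without the intensity trend, or after thinning to 2871 counts without ES replicate 2. The Tbx3 locus itself missed the threshold with quantile normalization (limma adjusted p = 0.246), under which Gm16063 reversed to -0.040, and without the trend (adjusted p = 0.176). The window count was 570 without ES replicate 1 (125 higher in ES cells and 445 in MEFs), 12 without ES replicate 2, 8 without MEF replicate 1 and 7 without MEF replicate 2. The locus count was 3 without either MEF replicate, when the calls at Tbx3os1 (adjusted p = 0.103 and 0.0978) and Gm16063 (0.124 and 0.33) ended. The Tbx3os1 call also ended at the lower-coordinate gene end (0.181). That at Gm16063 ended with a 5 kb flank (0.134), that at Gm16064 with a 5 kb flank (0.0899), and that at Tbx3os2 with median-centred values (0.0796).

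**Figure D4:**
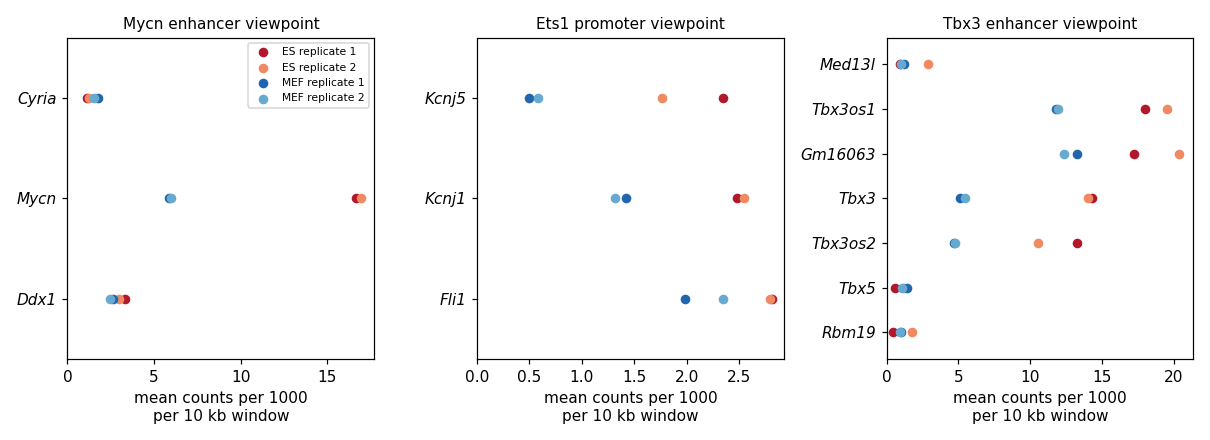
Mean counts per 1000 per 10 kb window over the locus of each tested list gene, 1 point per library, in a panel per viewpoint. At Mycn (16.8 in ES cells, 5.91 in MEFs) and Tbx3 (14.2 and 5.27) both ES points lie to the right of both MEF points, while at Med13l, Tbx5 and Rbm19 the points of the groups overlap or lie close together.

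The reach of contacts was described by the share of listed window counts that lay within 200 kb of the viewpoint. That span holds the called contacts at Mycn and Tbx3, while Kcnj5 and Kcnj1 lie beyond it. The share is therefore not independent of the window calls. From the Mycn enhancer this share was 66.6% ± 1.18 in ES cells and 57.8% ± 2.35 in MEFs (SD, n = 2 each), 8.87 points higher in ES cells. From the Tbx3 enhancer it was 70.7% ± 0.90 and 58.9% ± 0.66, 11.8 points higher in ES cells. The Ets1 promoter went the other way, with 55.0% ± 0.18 in ES cells and 59.9% ± 1.09 in MEFs, a difference of -4.90 points. As percent of the library total that difference was -10.4 points, since listed windows held 64.6% and 63.4% of the total in ES libraries and 76.6% and 74.4% in MEF libraries. It was 7.61 points for the Mycn enhancer and 8.35 for the Tbx3 enhancer. In each case both ES libraries lay on 1 side of both MEF libraries, and the two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. Of all counts in the shallowest library, ES replicate 2 of the Tbx3 enhancer, 46.2% lay within 200 kb (95% Clopper-Pearson interval 41.1 to 51.3%), against 45.8% in ES replicate 1.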

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

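The permutation of share differences, the tests of scaling and the tests with thinned libraries, with windows that do not overlap and with edgeR without ES replicate 2 were chosen only after the data had been seen.

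The share of contacts within 200 kb differed between ES cells and MEFs in opposite directions at different viewpoints, with both ES libraries above both MEF libraries from the Mycn and Tbx3 enhancers and below them from the Ets1 promoter. The ES minus MEF difference was 13.8 points larger for the Mycn enhancer than for the Ets1 promoter. For the Ets1 promoter minus the Tbx3 enhancer it was -16.7 points. A permutation of ES and MEF labels within each viewpoint gave p = 0.0556 for both, the smallest that the 36 arrangements can give. Groups that separate fully in opposite directions always give this value, so it adds nothing to the separation itself. The Mycn and Tbx3 enhancers differed by -2.97 points (permutation p = 0.611). These shares are of the listed windows; as percent of the library total the ES minus MEF differences were 7.61, -10.4 and 8.35 points for the Mycn, Ets1 and Tbx3 viewpoints, with the same signs.

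The higher contact of the Mycn enhancer with Mycn in ES cells did not follow library depth, since the library totals of both groups interleave. They were 88038 and 27290 counts in ES replicates 1 and 2, and 16774 and 59424 in MEF replicates 1 and 2. The peak window values were 31.2 and 29.1 in these ES libraries and 6.32 and 6.70 in these MEF libraries. Thinning all libraries to 16774 counts gave a log2 difference of 2.06 there, against 2.05 before. Thinning keeps the expected value of each window, so that result tests only the noise of fewer counts. A scaling error would move all windows by a similar amount, and the median log2 difference over all tested windows was -0.15. A strain variant in a single restriction site of the region would change the windows that hold it, and 18 called windows of the region do not overlap each other. A variant at the viewpoint itself was not tested. A contact between this enhancer and Mycn that is stronger in ES cells is therefore a hypothesis consistent with these tests. Cell line, strain background and medium may differ along with cell type and remain untested.

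Contacts of the Ets1 promoter shifted from the side of Kcnj5 and Kcnj1 in ES cells toward the other side in MEFs, apart from 42 MEF-higher windows on the former side, Gm31871 among them. After thinning to 13629 counts the calls fell from 414 to 266, while the median log2 differences over windows called before thinning did not shrink (smaller ratio of thinned to unthinned 1.01). Thinning keeps the expected value of each window, so this ratio tests only the noise of fewer counts. Other effects of depth cannot be told apart from cell type, since both ES totals (70629 and 206874) exceeded both MEF totals (13629 and 29638). No factor per library can move the share of values on the higher-coordinate side, which differed by -11.0 points (47.2% ± 0.73 in ES cells, 58.2% ± 1.74 in MEFs, SD, n = 2 each). This excludes a factor per library but no other form of normalization. In addition, 27 ES-higher and 31 MEF-higher called windows on opposite sides do not overlap, which argues against a variant in a single site that changes only the windows holding it. A variant at the viewpoint itself was not tested. A difference between cell types in how the Ets1 promoter divides its contacts between both sides may underlie this, as a hypothesis, and differences of strain and medium stay open and untested.

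The higher contact of the Tbx3 enhancer with Tbx3 in ES cells did not rest on chance counts of ES replicate 2, because without that library edgeR gave a log2 difference of 2.25 at the peak window with an adjusted p of 8.8e-07 (9.2e-09 to 0.411 over all alternatives of that window). That edgeR fit had ES replicate 1 as its only ES library, which is assumed to vary like the MEF libraries. The median log2 difference over all tested windows was -0.32, but it cannot decide on a scaling error. In ES replicate 2, 54.4% of listed windows had no count, and a factor per library cannot move those. The limma call ended without the intensity trend, under quantile normalization (adjusted p = 0.25) and, without ES replicate 2, after thinning to 2871 counts. Under quantile normalization and after thinning the log2 differences were 2.06 and 1.96 against 2.15 before, so that these losses came with a difference of similar size. In the region, 3 called windows do not overlap, more than a strain variant at a single restriction site was expected to change. That is fewer than the number set beforehand to argue against such a variant. This count therefore did not decide between the variant and a difference in contact. A cell-type difference in contact remains a possible explanation beside it.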

How the results depend on the processing

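Thinning, windows that do not overlap, gene ends, shares of the library total, the summed ES libraries and edgeR without ES replicate 2 were chosen only after the data had been seen. For regions, 407 comparisons with an alternative kept direction and side of the threshold, 82 fell short of it and 0 reversed. For gene loci 487 kept both, 100 fell short, 7 newly passed and 13 reversed. Regions whose peak window failed the filter in an alternative do not enter these counts. Regions had to separate the groups at the peak window, so leaving out 1 library or changing the pseudocount could not reverse them. Dropping the filter or the trend, or adding the block, leaves their log2 difference unchanged. The 0 reversals therefore rest largely on how regions were chosen. Of 35 regions, 27 were compared without ES replicate 1, 27 without ES replicate 2 and 28 without either MEF replicate. The counts also include near repeats of the main fit, such as windows within 2 Mb (32 of 32 kept). Called Mycn enhancer windows numbered 339 and moved to 214 without a filter, 184 with quantile normalization, 26 in bins of 20 kb, 37 among windows that do not overlap, and 216 to 273 leaving out 1 library; fewer windows are tested in the bins and among windows that do not overlap. Its called loci moved from 18 to 8 with quantile normalization and 8 to 17 leaving out 1 library. Ets1 promoter windows moved from 414 to 239 with quantile normalization, 33 in bins, 37 without overlap, 266 after thinning to 13629 counts, and 74 to 533 leaving out 1 library. Its loci moved from 12 to 5 with quantile normalization and 1 to 12 leaving out 1 library. Its share difference moved from -4.90 points to -6.39 without windows within 10 kb, -6.69 within 5 Mb and -10.4 as percent of the library total. Tbx3 enhancer windows moved from 21 to 43 with median centring, 0 with quantile normalization, 0 without a trend, 1 in bins, 37 with edgeR, 4 without overlap, 0 after thinning to 2871 counts without ES replicate 2, 12 with the ES libraries summed, and 7 to 570 leaving out 1 library. Its loci moved from 5 to 2 with quantile normalization, 0 without a trend, 3 with a flank of 5 kb and 3 to 7 leaving out 1 library. Its share difference moved from 11.8 points to 12.9 without windows within 10 kb and 8.35 as percent of the library total. Locus log2 differences reversed for Cyria at the lower gene end (0.088), under quantile normalization for Gm35155 (-0.33), Rpl21-ps2 (0.010), Gm38686 (0.021), 4921511I17Rik (0.035), Gm31928 (0.26) and Gm16063 (-0.040), and, among loci that pass no test, for Med13l (-0.14 without ES replicate 2 to 0.88 without ES replicate 1, -0.24 at the higher gene end), Tbx5 (-0.51 without ES replicate 2 to 0.0049 without ES replicate 1) and Rbm19 (-0.029 with a pseudocount of 0.25, -0.012 without MEF replicate 2 to 0.48 without ES replicate 1, -0.039 with a flank of 25 kb). Apart from the fewer windows or libraries named, the cause was not tested. Where 1 library is left out, the lone library is assumed to vary like the other group.

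The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.04, -0.01 and -0.09 for the Mycn, Ets1 and Tbx3 viewpoints. With the replicate block, limma called 396, 424 and 12 windows and 19, 10 and 5 loci. The calls at Fli1 (adjusted p = 0.0959), Gm31928 (0.0536) and Gm27162 (0.0501) and at the Tbx3 enhancer region from 119370001 (0.106) missed the threshold with the block, Ddx1 newly passed it (0.0383), and no other named call changed. Depth limits the Tbx3 enhancer most, where 54.4% of windows had no count in ES replicate 2.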

Other observations

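The balance of contacts on either side of a viewpoint, not among the planned comparisons and chosen after the values were seen, separated the groups at each viewpoint. Of the values between 10 kb and 1 Mb from the Mycn enhancer, 61.0% ± 0.88 lay on the higher-coordinate side, that of Mycn, in ES cells and 44.5% ± 0.61 in MEFs (SD, n = 2 each). For the Tbx3 enhancer, 45.8% ± 0.86 lay on the side of Tbx3 in ES cells and 31.9% ± 1.21 in MEFs. For the Ets1 promoter the higher-coordinate side, away from Fli1 and Kcnj1, held 47.2% ± 0.73 in ES cells and 58.2% ± 1.74 in MEFs. Called windows followed the sides: from the Mycn enhancer 170 of 182 ES-higher windows lay on the side of Mycn and 132 of 157 MEF-higher windows on the other. From the Ets1 promoter 159 of 162 ES-higher windows lay on the side of Fli1 and 210 of 252 MEF-higher windows on the other.

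Between 50 and 200 kb from the viewpoint the share of values was higher in ES cells for both enhancers, at 36.4% ± 0.71 in ES cells and 25.5% ± 0.55 in MEFs from the Mycn enhancer and 30.3% ± 0.81 and 22.4% ± 0.89 from the Tbx3 enhancer (SD, n = 2 each). Within 50 kb of the Mycn enhancer the shares were 30.1% ± 0.48 in ES cells and 32.1% ± 1.82 in MEFs, and within 50 kb of the Tbx3 enhancer 40.3% ± 1.69 and 36.4% ± 1.54. Between 200 kb and 1 Mb from the Tbx3 enhancer the shares were 24.7% ± 0.95 in ES cells and 38.3% ± 0.03 in MEFs. Listed windows held 64.6% and 63.4% of the library total in the ES libraries of the Ets1 promoter and 76.6% and 74.4% in its MEF libraries. For the Mycn enhancer these shares were 76.3% and 75.9% in ES cells and 75.1% and 74.8% in MEFs.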
